A study of Homo sapiens with 10 samples.

How the data were processed

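Gene expression was measured on Affymetrix arrays in 10 samples that the labels describe as human hepatocellular carcinoma xenografts or cells. The groups, taken from the sample titles, were parental xenografts (3 arrays, replicates 1, 3 and 4), sorafenib-resistant xenografts (5 arrays, replicates 1 to 5), parental Huh7 cells (1 array) and sorafenib-resistant Huh7 cells (1 array). Per the labels' protocols, 100 ng of total RNA was labelled per sample, resistant cells were kept in 10 µM sorafenib that was renewed every 72 h over more than 6 months, and all animals received a solution of 60 or 100 mg/kg by gavage for at least 2 weeks. The labels did not name the content of that solution, the dose of each animal, whether parental and resistant tumours were exposed alike, the line from which the xenografts were grown, or whether the xenograft samples came from separate animals. The extraction protocol in the labels names a brain region of a patient as the source of the RNA, which does not match xenografts or a cell line, and the origin of that text is not given in the sources used here. The p-values measure the spread between these samples, which may be partly technical.

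The deposited values were intensities per probe set, 1 column per array. Per the submitters' processing notes, the authors made them with RMA, a method that corrects the background, normalizes between arrays and summarises the probes of each probe set. The version of RMA, its settings and whether all 10 arrays were normalized together are not given in the sources used here. RMA usually gives log2 values. The deposited intensities were on a linear scale, with no negative value, array minima of 2.35 to 2.56 and maxima of 11289 to 12768. Log base 2 was therefore taken before any test, and no pseudocount was needed. Medians of the 10 arrays lay between 16.8 and 17.6, so no array-wide shift was left to correct. RMA compresses differences between dim probe sets, so a fold change that starts from a level near the array median or below can understate the change. The size of such a change is uncertain.

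The table held 54613 probe sets. In the platform annotation, 41091 of these had 1 gene symbol, 1801 had several and 11721 had none. Of the probe sets with 1 symbol, 41037 were matched through their Entrez identifier to the current gene table, and 0 symbols changed. Probe sets with several symbols or none were left out of the gene tests, as were 59 probe sets of sex-linked genes. Each gene was represented by its probe set with the highest mean over all 10 arrays, which gave 19740 genes, of which 10511 had more than 1 probe set. No filter on dim genes was applied in the main test. No genome build is named for the array, and no coordinates are given here.

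The xenograft groups were compared with limma 3.58.1 in R 4.3.3, by a linear model per gene (lmFit) and a moderated two-sided test with an intensity trend (eBayes), on the 8 xenograft arrays alone. The threshold was a Benjamini-Hochberg adjusted p of 0.05 over all genes tested. Gene lists were compared with camera, also from limma, with a preset correlation between genes of 0.01 and adjustment over 43 lists of at least 5 measured genes. There were 32 pathway lists, 9 lists of markers of other cell types and 2 lists on RNA quality and reference genes. The lists held 871 distinct genes, of which 790 were measured, and the others were not analysed here. Camera was repeated with a correlation estimated for each list, and the lists were also tested with fry and, as a later addition, by exact permutation of the list mean over the 56 splits of the 8 arrays into groups of 3 and 5. The Huh7 groups had 1 array each, so differences of log2 values are given with no test. The median of each list in Huh7 was placed among 10000 random lists of the same size, matched on level. The agreement of xenograft and Huh7 changes was measured by Pearson's r and Spearman's rho across genes, with an exact two-sided permutation over the same 56 splits. A contrast of the xenograft change minus the Huh7 change was fitted with limma on all 10 arrays. In that fit the spread came from the xenograft arrays, and the lone Huh7 arrays were assumed to vary like them, so its threshold cannot call a difference between 2 single cultures.

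Groups, main tests, gene lists, most of the other fits and the rule for named genes were fixed before the data were examined. The exact permutation of list means, the early-response mean as a covariate and the fits without 2 arrays together were added after the data had been seen. For xenografts the rule named the 12 largest rises and 12 largest falls among genes past the threshold whose groups did not overlap, or all of them where fewer passed. For each list it named up to 4 members with the smallest p. For Huh7 it named the 12 largest rises and 12 largest falls among genes brighter than the median on 1 of the 2 arrays. For the agreement it named up to 8 genes of the same sign and 8 of opposite sign that passed the threshold in xenografts and differed by at least 1 on the log2 scale in both settings, and for the contrast it named 4 genes in each direction. XIST and Y-linked genes were left out.

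The test was checked on simulated values for the xenograft comparison, with 200 of 19740 genes changed, all drawn from genes above the median level. It recovered 87% of genes changed by 1 on the log2 scale and 100% of those changed by 2, with 9 false calls, or 4.59% of its calls. It made 0 calls in values with no change, and camera called 2 of 2 shifted lists and 0 of the others. In these simulated values genes varied independently of each other and no array stood apart from its group. The check therefore does not bear on the recovery of dim genes, on correlated lists or on arrays that stand apart. The alternatives covered a filter on dim genes, the mean of a gene's probe sets, repeated quantile normalization, centring on the median, the variance prior, array weights, the replicate number as a block, the probe set level, the threshold, other tests and the removal of each xenograft array in turn. No pair of arrays was a duplicate, with standard deviations of the log2 difference of 0.257 to 0.370 within groups. For arrays, the number of samples limits the precision. Figures were drawn with matplotlib.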

Results

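The series compared hepatocellular carcinoma, the main primary liver cancer, before and after it had become resistant to sorafenib, an oral inhibitor of several kinases that is given for this cancer. Expression was measured in tumours grown in mice (xenografts), with 3 parental and 5 resistant samples, and in Huh7, an established human hepatocellular carcinoma cell line, with 1 parental and 1 resistant sample. Median intensities of the arrays ranged from 16.8 to 17.6. Over all genes, the standard deviation of the log2 difference was 0.257 to 0.370 between xenografts of the same group, 0.297 to 0.453 between xenografts of different groups, and 0.565 between the Huh7 arrays. On the first principal component of the xenograft arrays, which held 34.0% of the variance, parental replicates 1 and 4 lay at -27.9 and -22.4. Parental replicate 3 lay at 4.55, within the range of the resistant arrays (-3.99 to 32.9), and resistant replicate 2 lay at 32.9, far from the others of its group.

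The first question was which genes differed between resistant and parental xenografts. In resistant xenografts 12 genes were higher and 4 were lower, of 19740 genes tested with limma. The largest rises were in SERPINE2, a secreted inhibitor of serine proteases (log2 fold change 2.50 ± 0.36 SE, 5.66-fold, adjusted p = 0.0340), CGA, the alpha subunit shared by the glycoprotein hormones (2.46 ± 0.36 SE, 5.52-fold, adjusted p = 0.0340), and GJA1, a gap junction connexin (2.45 ± 0.25 SE, 5.47-fold, adjusted p = 0.00374). LYZ, the antibacterial enzyme lysozyme, had the smallest adjusted p (0.000641). Its log2 level was 8.19 ± 0.09 (SD, n = 3) in parental and 10.1 ± 0.34 (SD, n = 5) in resistant xenografts, a 3.85-fold rise. PLA2G2A, a secreted phospholipase, rose by 1.77 ± 0.28 SE on the log2 scale, and OSBPL10, of the oxysterol-binding protein family, rose by 1.62 ± 0.21 SE.

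The other 6 genes that rose were C12orf75 (log2 fold change 1.39), the lipoprotein receptor VLDLR (1.38), the collagen-binding integrin subunit ITGA2 (1.31), SRPX (1.23), the tetraspanin TSPAN8 (0.98) and the Notch coactivator MAML2 (0.84), with adjusted p from 0.0196 for SRPX to 0.0469 for MAML2. The 4 genes that fell were FAM3B, which encodes a secreted protein (log2 fold change -1.17 ± 0.19 SE, 2.24-fold lower, adjusted p = 0.0469), FRAT1, a positive regulator of Wnt signalling (-1.03 ± 0.11 SE, 2.04-fold lower, adjusted p = 0.00596), the zinc finger factor ZIC5 (-0.98, adjusted p = 0.0340) and the long noncoding RNA LINC00473 (-0.92, adjusted p = 0.0469). In all 16 genes the 5 resistant arrays lay on 1 side of the 3 parental arrays. Over all genes 1350 (6.84%) were separated in this way, against 3.57% by chance. SERPINE2, GJA1, VLDLR and MAML2 had parental means of 3.87, 3.74, 3.24 and 2.45, below the array medians of 4.07 to 4.14 on the log2 scale.

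Of the 16 genes, 6 had more than 1 probe set. For LYZ both gave a similar rise (1.95 and 2.18). For SERPINE2, CGA and ITGA2 the dimmer probe set gave 0.13, 0.15 and 0.30, and for OSBPL10 and MAML2 at least 1 dimmer probe set had the opposite sign, the lowest at -0.18 and -0.22. The number of changed genes depended on single arrays: it was 1 without parental replicate 1, 118 without parental replicate 3, 8 without parental replicate 4, and 6, 5, 4 and 7 without resistant replicates 2, 3, 4 and 5, and LYZ alone of the 16 passed in all 8 of these fits. It was also 10 when dim genes were left out, 10 after repeated quantile normalization and 6 with the mean of probe sets per gene. It was 7 without the intensity trend, 44 with array weights and 29 at the level of probe sets. A fit of all 10 arrays, which estimates a resistance effect shared by xenografts and Huh7, gave 6. At an unadjusted p of 0.05 limma gave 2128 genes between the xenograft groups.

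**Figure D1:**
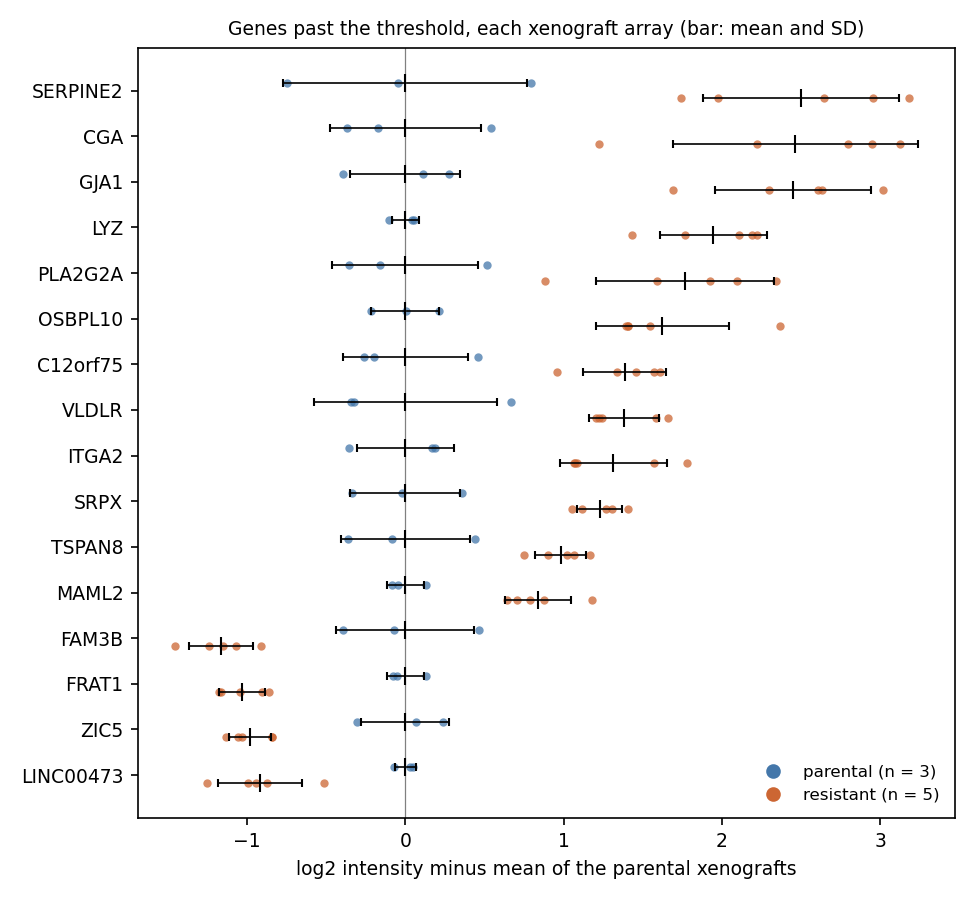
Each row is 1 of the 16 genes past the threshold; points are the log2 intensity of single xenograft arrays minus the mean of the 3 parental arrays (blue, parental; orange, resistant), with the mean and SD of each group as a bar. Resistant and parental arrays do not overlap for any of these genes, and the mean shift runs from 2.50 for SERPINE2 to -1.17 for FAM3B.

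Of the 43 gene lists, 12 passed the camera threshold with the preset correlation, 8 higher and 4 lower in resistant xenografts. None of these calls held with an estimated correlation (0 of 43 lists, smallest adjusted p = 0.697), where 1 list passed an unadjusted p of 0.05. Fry called 0 lists as well for a shift in 1 direction, with 2 unadjusted. Its mixed test, which counts changes of members in either direction, passed 2 lists after adjustment. These were interferon-stimulated genes (adjusted p = 0.00345) and leukocyte markers (1e-05), a list that holds LYZ. Exact permutation of the list means gave 3 lists unadjusted and 0 after adjustment (smallest adjusted p = 0.384). The smallest p that the splits can give is 0.0179. After adjustment over 43 lists none could pass unless many lists lay at that p. The 0 calls after adjustment therefore decide nothing. Before adjustment the permutation p of the lists that camera called was 0.0179 for interferon-stimulated genes. For the others it ran from 0.0714 for mesenchymal transition to 0.518 for hepatocyte differentiation, short of 0.05. The remaining lists under 0.05, receptor kinases and growth factors (0.0179) and liver progenitor and stemness genes (0.0357), were not called by camera. The list of early-response and heat-shock genes, which often rise with tissue handling, was itself among the higher lists (camera adjusted p = 0.0168; adjusted p = 0.703 with an estimated correlation). Its score relative to the parental mean was 0.47 in parental replicate 3 and 0.95 in resistant replicate 2, against -0.27 and -0.20 in the other 2 parental arrays. Of its 13 measured members none passed over all genes, and HSPH1 and DNAJB1, a heat shock protein and a co-chaperone, passed when adjusted over the list alone (log2 fold changes 1.07 and 1.13). This call was lost without parental replicate 1 (adjusted p = 0.224), parental replicate 4 (0.142), resistant replicate 2 (0.163) or resistant replicate 5 (0.0519).

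Genes of the unfolded protein and integrated stress responses, which act when protein folding or amino acid supply fails, were higher as a list, with 26 of 28 members above the parental mean and a mean log2 change of 0.33 (camera adjusted p = 1.88e-09; adjusted p = 0.703 with an estimated correlation; exact permutation p = 0.107). Over all genes 1 member rose, VLDLR, and 27 did not pass. Adjusted over the list alone 3 rose: VLDLR, the endoplasmic reticulum co-chaperone DNAJB9 (log2 fold change 0.84 ± 0.14 SE) and the disulfide isomerase PDIA6 (0.25). PDIA4, a related isomerase, changed by 0.30 and did not pass. Hypoxia response genes were also higher, with 22 of 24 members above the parental mean and a mean log2 change of 0.38 (camera adjusted p = 7.95e-08; adjusted p = 0.703 with an estimated correlation; exact permutation p = 0.0893). None of them passed over all genes, and 2 rose when adjusted over the list alone: EGLN3, an oxygen-sensing prolyl hydroxylase (1.52 ± 0.27 SE, 0.0713 over all genes and 0.00217 within the list), and VEGFA, the vascular growth factor (0.48 ± 0.13 SE). INSIG2 (0.57) and STC2 (1.15) did not pass. The mean change of the hypoxia list was 0.25 without parental replicate 1 and 0.59 without parental replicate 3. Scores of the early-response list moved in the same arrays: parental replicate 3 had the highest parental score of both lists (0.29 and 0.41) and resistant replicate 2 the highest of all arrays (0.60 and 0.55). Only in resistant replicate 1 did the early-response score (-0.18) differ in sign from both lists (0.17 and 0.28). Both lists still passed camera with the early-response mean as a covariate, a fit chosen after the data had been seen. Their mean changes were then 0.20 ± 0.075 SE and 0.28 ± 0.16 SE.

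Proliferation genes had a mean log2 change of 0.21, with 25 of 36 members higher (camera adjusted p = 0.000218; adjusted p = 0.703 with an estimated correlation). Over all genes 0 of them passed, and TOP2A, a DNA topoisomerase (0.56 ± 0.11 SE), and AURKA, a mitotic kinase (0.52 ± 0.13 SE), rose when adjusted over the list alone. Glycolysis genes (15 of 18 higher, camera adjusted p = 0.0128; adjusted p = 0.703 with an estimated correlation) held 0 members past either threshold. The largest among those with the smallest p was the phosphofructokinase PFKP (0.79 ± 0.28 SE). Metallothioneins, which bind zinc and copper, were higher in 7 of 8 members (camera adjusted p = 0.0128; adjusted p = 0.703 with an estimated correlation), with values of 0.60 for MT2A and 0.29 for MT1G, neither past the threshold. The proliferation scores moved with the early-response list in the arrays that stood apart, with 0.28 in parental replicate 3 and 0.63 in resistant replicate 2. In resistant replicates 1, 4 and 5 the signs were opposite. Proliferation was at 0.31, -0.09 and -0.01 there, and early response at -0.18, 0.42 and 0.36. On the other arrays the signs were the same. With the early-response mean as a covariate, a fit chosen after the data had been seen, the calls of proliferation (adjusted p = 0.0599, mean 0.12) and glycolysis (0.255, mean 0.09) were lost. The proliferation call was also lost without parental replicate 1 (adjusted p = 0.104, mean 0.11) or resistant replicate 2 (0.106, mean 0.11), and its mean was 0.35 without parental replicate 3, where the call of metallothioneins was lost (0.0673). The glycolysis call was lost without parental replicate 1 (0.342), parental replicate 4 (0.237) or resistant replicate 2 (0.155), and with the mean of probe sets per gene (0.0812).

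Cholesterol synthesis genes had 13 of 16 members higher (camera adjusted p = 0.0201; adjusted p = 0.703 with an estimated correlation), with values of 0.37 for NSDHL, 0.41 for SQLE and 0.39 for INSIG1, none past either threshold. Genes of mesenchymal transition had 17 of 24 members higher (camera adjusted p = 0.0240, and adjusted p = 0.703 with an estimated correlation). No member passed over all genes. Adjusted over the list alone 2 of them rose: VIM, the intermediate filament protein vimentin (1.15 ± 0.29 SE), and S100A4, a calcium-binding protein (1.09 ± 0.28 SE). LOX (0.92) and ZEB1 (0.55) did not pass. The cholesterol call was lost without parental replicate 1 (adjusted p = 0.104), parental replicate 4 (0.186) or resistant replicate 5 (0.153). With the early-response covariate the calls of cholesterol synthesis (0.115, mean 0.10 in place of 0.14) and mesenchymal transition (0.114, mean 0.16 in place of 0.21) were lost too, with most of both shifts left. The mesenchymal call was also lost without parental replicate 1 (0.120), parental replicate 4 (0.0790), resistant replicate 4 (0.0637) or resistant replicate 5 (0.0637).

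Interferon-stimulated genes were lower as a list, with 23 of 29 members below the parental mean and a mean log2 change of -0.22 (camera adjusted p = 0.00012; adjusted p = 0.697 with an estimated correlation). The exact permutation p was 0.0179 before adjustment. Over all genes 0 passed, and adjusted over the list alone 6 fell and 1 rose. Those with the smallest p were the antiviral helicase-like DDX60 (-0.61 ± 0.13 SE), CMPK2 (-0.72), IFIT1 (-0.75) and HERC6 (-0.76). DDX60 (2.75 in parental and 2.15 in resistant xenografts) and CMPK2 lay below the array medians in both groups, where the size of a change is uncertain. Oxidative phosphorylation genes had 26 of 34 members lower, by a mean of -0.08 (camera adjusted p = 0.00397; adjusted p = 0.703 with an estimated correlation), with 0 members past either threshold and values of -0.31 for ATP5MC1 and -0.30 for NDUFV1. Genes of hepatocyte differentiation had 23 of 31 members lower (camera adjusted p = 0.0207, and adjusted p = 0.703 with an estimated correlation). No member passed over all genes. Adjusted over the list alone 2 fell: ASS1, a urea cycle enzyme (-0.21 ± 0.05 SE), and the fibrinogen chain FGA (-0.37 ± 0.10 SE). Complement and coagulation genes had 17 of 26 members lower (camera adjusted p = 0.0366, and adjusted p = 0.703 with an estimated correlation). No member passed over all genes. Adjusted over the list alone 3 fell (C9, KNG1 and F7, by -1.43, -1.05 and -0.43) and 1 rose (MBL2, 0.66). MBL2 lay below the array medians in both groups, and C9 in resistant xenografts (3.22). With the early-response covariate the calls of the hepatocyte list (adjusted p = 0.171, mean -0.07 in place of -0.12) and the complement list (0.255, mean -0.14 in place of -0.21) were lost. In the arrays that stood apart, parental replicate 3 and resistant replicate 2, the hepatocyte scores were -0.20 and -0.35 and the complement scores -0.34 and -0.37, and resistant replicate 1, with a low early-response score of -0.18, had -0.32 and -0.38. The hepatocyte call was also lost without parental replicate 1 (adjusted p = 0.106), parental replicate 4 (0.333), resistant replicate 1 (0.223) or resistant replicate 2 (0.196), with the mean of probe sets per gene (0.110) and without the intensity trend (0.0721). The complement call was also lost without parental replicate 1 (0.104), parental replicate 4 (0.880), resistant replicate 1 (0.154) or resistant replicate 2 (0.163), with the mean of probe sets per gene (0.0834) and without the intensity trend (0.0554).

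**Figure D2:**
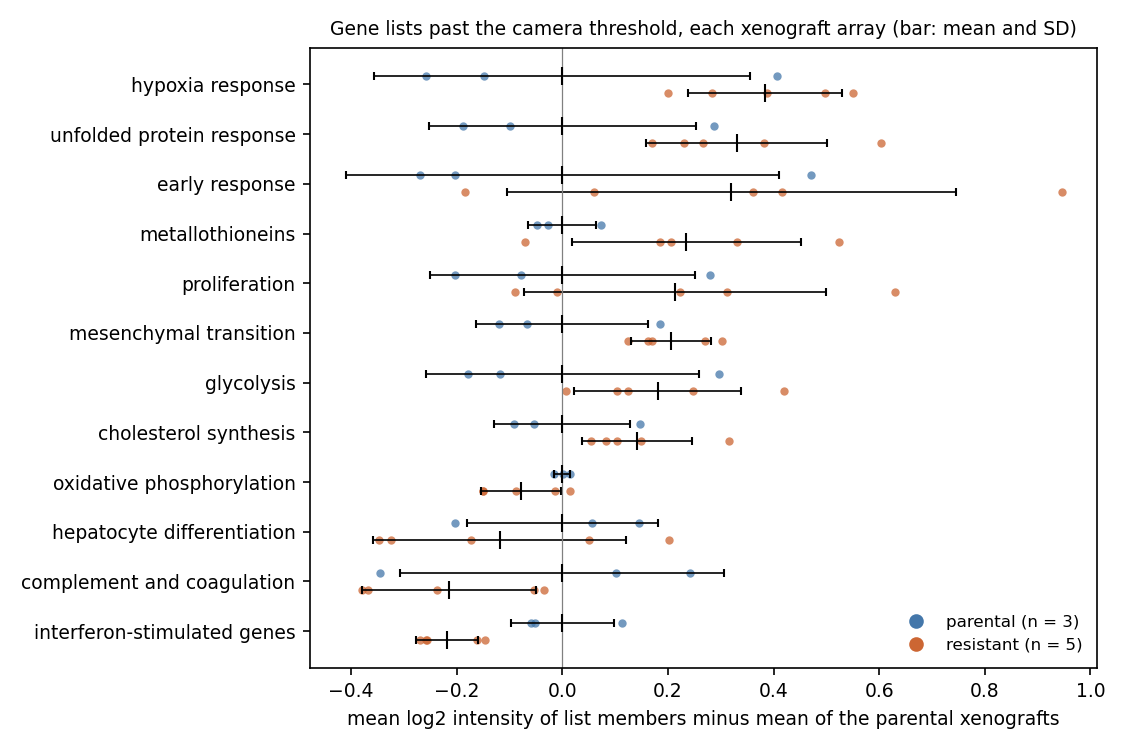
Each row is 1 of the 12 gene lists past the camera threshold; points are the mean log2 intensity of the list's members on single xenograft arrays minus the mean of the 3 parental arrays (blue, parental; orange, resistant), with the mean and SD of each group as a bar. For most lists parental replicate 3 lies among the resistant arrays, as with hypoxia response, where it is at 0.41 and the resistant arrays run from 0.20 to 0.55.

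Neither the kinases that sorafenib inhibits nor the drug efflux transporters passed as lists, with camera adjusted p of 0.278 and 0.536. Lists of endothelial cells, fibroblasts, pericytes, leukocytes, red cells, fat, skin, muscle and brain, which stand for other cells that a xenograft or a sample could hold, had camera adjusted p from 0.242 to 0.941. Without parental replicate 1 the skin list passed (adjusted p = 0.00342, mean 0.30 against 0.14 with all arrays), since that array had the highest score for it (0.32). LYZ, which is also a leukocyte marker, was the 1 member of these lists past the threshold over all genes, while the leukocyte genes PTPRC and TYROBP lay at 2.33 and 4.08 in resistant xenografts and differed by 0.01 and -0.16 from parental ones, short of the threshold. Host cells of a xenograft are from the mouse and are read here only through human probe sets. These lists and genes therefore cannot show whether such cells were absent or unchanged, or whether LYZ came from them. The reference genes had a mean change of 0.06 (camera adjusted p = 0.220), and passed without resistant replicate 5 (0.0499, mean 0.09). The abundant liver products lay near the top of the measured range, where a change can be hidden: ALB, encoding albumin, was at 13.4 ± 0.06 (SD, n = 3) and 13.3 ± 0.08 (SD, n = 5) and AFP, the fetal liver protein alpha-fetoprotein, was at 13.4 ± 0.10 and 13.3 ± 0.11, with at least 99.9% of genes below AFP on every xenograft array.

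The second question was how resistant Huh7 cells differed from parental ones. With 1 array each there was no spread to set a difference against, and no test was made. Of 19740 genes, 785 were higher and 528 lower by at least 2-fold in resistant Huh7 cells, 6.65% in all. The largest increases were in CEMIP, which takes part in the breakdown of hyaluronan (log2 difference 5.82, from 3.59 to 9.41), AGR2, a disulfide isomerase of secretory cells (5.77), the sulfotransferase SULT1C2 (5.50), SYTL2 (5.47), AMIGO2 (5.30) and TMEM37 (5.22). C19orf33, the fatty acid binding protein FABP1, DPYSL2, TUBAL3, the hyaluronan receptor CD44 and LY96 followed, with differences of 4.64, 4.41, 4.28, 4.25, 4.13 and 3.99. The largest decreases were in BEX1 (-5.17), AMBP, a precursor of plasma proteins made by hepatocytes (-4.83, from 11.7 to 6.91), G6PC1, the catalytic subunit of glucose-6-phosphatase (-4.26), CRH (-4.20), EPHA7 (-3.95), the apolipoprotein APOA2 (-3.95) and the glucose transporter SLC2A2 (-3.90). ZNF804A, PDE3A, HS3ST3B1, LRP8 and ACADL had differences of -3.47, -3.45, -3.37, -3.36 and -3.36.

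The gene lists of Huh7 are given as a description of these 2 arrays. Hypoxia response genes had a median log2 difference of 0.83, with 10 of 24 members higher and 0 lower by at least 2-fold, above 100% of random lists matched on level. Metallothioneins had a median of 1.04, with 4 of 8 members higher by at least 2-fold, among them MT1X (2.36) and MT2A (2.01). Genes of the unfolded protein and integrated stress responses had a median of -0.95, with 14 of 28 members lower and 0 higher by at least 2-fold, below all random lists. Among them ASNS, which makes asparagine, differed by -2.17 and ATF3 by -2.56. Genes of hepatocyte differentiation had a median of -0.47, with 12 of 31 members lower and 3 higher by at least 2-fold. Proliferation genes had a median of 0.46, with 6 of 36 higher and 1 lower by at least 2-fold. Oxidative phosphorylation genes had 0 of 34 members that differed by 2-fold in either direction. Abundant liver products were not all alike on the Huh7 arrays. ALB lay at 7.30 in parental and 4.69 in resistant cells and AFP at 6.53 and 5.22, far below their xenograft levels, while SERPINA1, which encodes a protease inhibitor of plasma, lay at 12.9 and 12.8, close to its level of 13.6 in xenografts. AMBP and APOB, an apolipoprotein, lay at 11.7 and 11.4 in parental Huh7 cells, against 12.4 for both in parental xenografts.

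The third question was whether resistance went with the same changes in xenografts and in Huh7. Across 19740 genes, which are not independent replicates, the xenograft log2 fold changes and the Huh7 differences had a Pearson r of 0.100 (exact permutation p = 0.125, 7 of 56 splits as large) and a Spearman rho of 0.013 (exact permutation p = 0.750). These were 2 relations, and neither passed before adjustment. Over all genes 49.9% had the same sign in both settings. Of the 16 genes changed in xenografts, 13 had the same sign in Huh7, 10 of them higher and 3 lower, which counts GJA1 with a Huh7 difference of 0.03. Across these 16 genes r was 0.163 (exact permutation p = 0.536). Of these genes 7 differed by at least 2-fold in both settings. SERPINE2 (2.50 in xenografts, 3.20 in Huh7), ITGA2 (1.31 and 2.79), OSBPL10 (1.62 and 1.30), SRPX (1.23 and 1.66) and FRAT1 (-1.03 and -1.43) had the same sign, and CGA (2.46 and -2.86) and LYZ (1.95 and -1.60) had opposite signs.

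**Figure D3:**
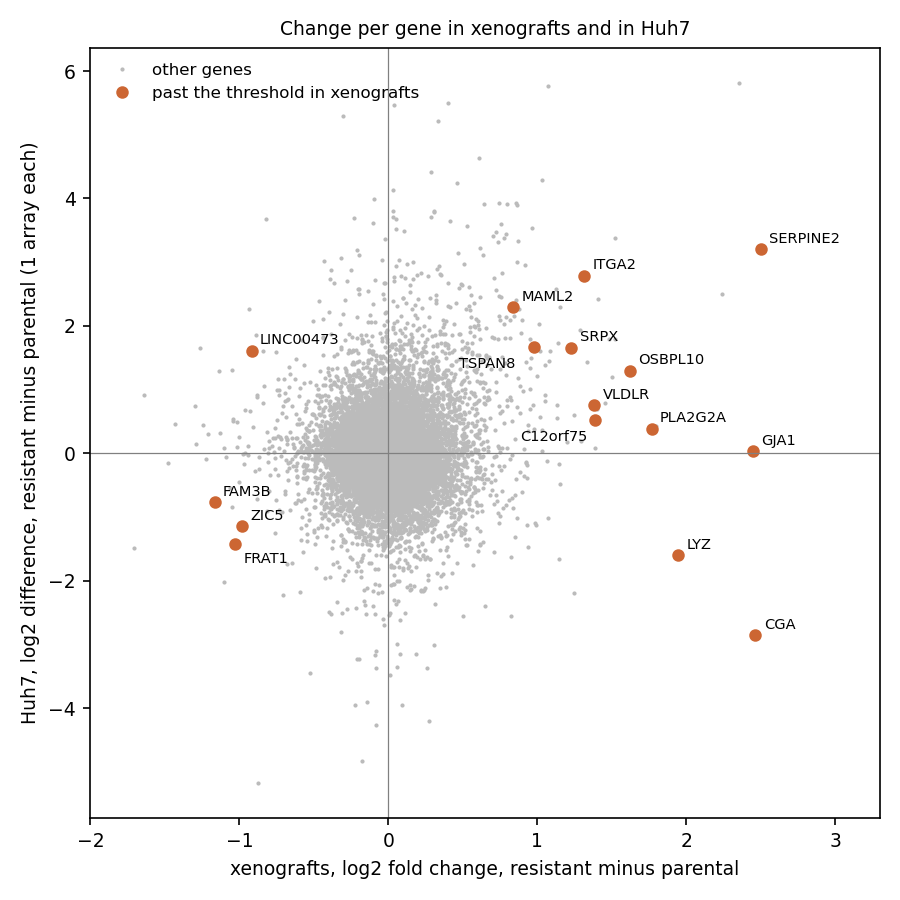
Each point is 1 of 19740 genes, with its xenograft log2 fold change (5 resistant minus 3 parental arrays) on the horizontal axis and its Huh7 log2 difference (1 array each) on the vertical axis; the 16 genes past the threshold in xenografts are in orange. SERPINE2 and ITGA2 lie high in both, while CGA and LYZ are higher in resistant xenografts and lower in resistant Huh7 cells.

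The xenograft change minus the Huh7 change can only be described, since Huh7 had 1 array per group. The log2 difference between its arrays had a standard deviation of 0.565, against 0.297 to 0.453 between xenografts of different groups. Both include the change with resistance, so neither gives the spread of Huh7 replicates. If the Huh7 arrays varied like the xenografts, which cannot be checked, 1105 genes would lie past the limma threshold, with the xenograft change the higher for 530 and the lower for 575. The genes named in the first direction encode liver secretory products: APOA2 (4.04), AMBP (4.66), ALB (2.57) and the fibrinogen chain FGG (3.03). Their xenograft changes were 0.09, -0.17, -0.04 and -0.20 on the log2 scale, and their Huh7 differences -3.95, -4.83, -2.61 and -3.23. In parental xenografts APOA2 and ALB lay at 13.1 and 13.4, near the top of the measured range, where a xenograft change can be hidden. In the other direction were FABP1 (-4.13), SYTL2 (-5.43), CD44 (-4.10) and TMEM37 (-4.88), whose xenograft changes were 0.29, 0.04, 0.03 and 0.33. The number was 729 without parental replicate 4.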

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

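The tests of the gene count over other splits, of level-matched lists, of single arrays, of the list means over splits, of array-wide signal and of another line were chosen after the results they concern had been seen, as were the comparisons with 2 SE for the early-response covariate and for single arrays. The tests of the list count over splits, of that covariate by camera and of mixed cells were written down before their results were seen, the wider test of mixed cells after the narrower one had left 3 genes.

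For OSBPL10 the 5 resistant xenografts held 1 value far from the others, with a gap of 0.848 of the group's range. This was 1 of 28 such groups examined, and chance gives about 1 in 20. For 1105 genes the xenograft change minus the Huh7 change lay past a threshold that takes its spread from the xenografts alone. With 1 array per Huh7 group, this does not call a difference between the settings. By gene, the xenograft change minus the Huh7 change was 4.04 for APOA2, 4.66 for AMBP, 2.57 for ALB, 3.03 for FGG, -4.13 for FABP1, -5.43 for SYTL2, -4.10 for CD44 and -4.88 for TMEM37. Of the 16 genes changed in xenografts 5 lay past the same threshold, with values of 5.32 for CGA, 2.42 for GJA1, 3.54 for LYZ, -1.45 for MAML2 and -2.53 for LINC00473. In probe sets without a single gene symbol, which the comparisons of genes do not use, 4 of 13522 passed the threshold between the xenograft groups, 1 higher and 3 lower.

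Chance is argued against for the number of changed genes, and not for the number of shifted lists. Of the 56 splits of the 8 xenograft arrays into 3 and 5, 1 gave as many as 16 genes, the real one, and the highest of the others gave 9. For the lists, 13 of the 56 splits gave 12 or more, and the highest of the others gave 17.

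The higher scores of the unfolded protein and hypoxia lists in resistant xenografts were weighed against technical explanations. A trend with brightness is argued against by the level-matched random lists, of which 100% lay below both medians. A single array as the cause stays open. Both lists passed camera with the preset correlation in 8 of 8 fits without 1 array. But the mean change lay within 2 SE of 0 in 4 of these fits for the first list and 5 for the second (0.255 ± 0.182 SE for hypoxia without parental replicate 1). With so few arrays 2 SE is a narrow limit, and a wider one would hold at least as many fits. With an estimated correlation neither list passed on all arrays (adjusted p = 0.703 for both), and fry called 0 of 43 lists for a shift in 1 direction. The exact permutation also called 0 after adjustment, but its smallest possible p is too large for a few lists to pass, so that count decides nothing. With the early-response mean of each array as a covariate both lists still passed camera (larger adjusted p = 6.40e-06), but their mean changes went from 0.330 ± 0.147 (SE) to 0.202 ± 0.075 and from 0.384 ± 0.173 to 0.279 ± 0.159. The second lies within 2 SE of 0, and 13 of 56 splits gave as many lists by camera, so a response to handling stays open. The spread between arrays alone also stays open, since 6 of 56 splits gave as large a mean for the first list and 5 of 56 for the second, and so does resistance itself. Drug exposure at sampling stays open as well, untested, since the labels do not say whether parental and resistant tumours were exposed alike, and this holds for every change between the xenograft groups.

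Of the genes that rose in resistant xenografts, SERPINE2, GJA1, OSBPL10, C12orf75 and VLDLR were more than 4-fold brighter on the Huh7 parental array than in parental xenografts, and a candidate explanation is that cells like those on the Huh7 arrays were mixed into the resistant tumours. The rise of GJA1 would need 3.61% of the Huh7 level, and those of the other 4 genes 9.84% to 19.9%. Among the 10 other genes that were bright on both Huh7 arrays and well below them in parental xenografts, the median rise was 1.48% (95% bootstrap interval 0.14 to 3.14), and 0 of them reached 9.84%, which argues against such cells as the cause for those 4 genes. For GJA1 this stays open, since 3 genes were left for a test at its level, with a median of 3.12% (interval 1 to 9.84), too few to decide. A change of these genes within the resistant tumour cells stays open too.

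The arrays labelled Huh7 held some liver secretory genes at far lower levels than the xenografts, with 12 of 31 hepatocyte genes lower by at least 4 on the log2 scale in parental cells, while others stayed bright there (SERPINA1 12.9, AMBP 11.7, APOB 11.4, FGG 11.2 and APOA2 11.2), as in cells of liver origin. The 12 reference genes had a median difference of -0.0235, so the deposited values hold no array-wide shift. Whether the raw signal was low cannot be told from this, since RMA normalizes between arrays. Huh7 is known as a producer of albumin and alpha-fetoprotein, and on the Huh7 parental array 63.2% of genes lay below AFP, against at least 99.9% on every xenograft array. Another liver line than the labelled one could give that level, and so could a culture of Huh7 that had lost these transcripts. The labels hold nothing that would decide, and the difference between culture and tumour stays among the open explanations, untested.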

How the results depend on the processing

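The fits without parental replicate 3 and resistant replicate 2 together, the exact permutation of list means and the early-response covariate were chosen after seeing the data, and the other alternatives were planned. The count of 16 changed genes was 10 with dim genes left out, 6 with the mean of probe sets per gene, 10 after repeated quantile normalization and 7 with no intensity trend. It was 44 with array quality weights, 29 over all probe sets and 0 by Welch's test (1619 unadjusted). All 10 arrays, fitted with a resistance effect shared by xenografts and Huh7, gave 6. Without parental replicate 3 and resistant replicate 2 the count was 125, which kept 12 of the 16. It ranged from 1 to 118 without single arrays, and fewer arrays change both the spread and the means. It was 17 after centring, 16 with a robust prior (13 of them the same genes) and 12 with a fold of at least 2 as well. The count of shifted lists, 12, ranged from 6 to 16 without single arrays. It was 0 with an estimated correlation and 0 with fry for a shift in 1 direction. It was 0 by exact permutation, where a few lists at the smallest possible p cannot pass after adjustment. With the early-response covariate it was 6. That fit kept 5 of the 12 calls. It lost 6 others and, by construction, that of the early-response list itself, whose mean is the covariate, and its added call was NRF2 targets (adjusted p = 0.0445). The lists of unfolded protein, hypoxia, interferon-stimulated and oxidative phosphorylation genes passed camera with the preset correlation in all 8 fits without single arrays. The 1313 genes that differed in Huh7 were 240 at a difference of at least 2 on the log2 scale, a stricter threshold by construction. The correlation of 0.100 ranged from 0.075 to 0.163 over all alternatives, with exact permutation p from 0.095 to 0.536. The 1105 genes of the contrast ranged from 729 to 1232 without single arrays. For the other changes the cause was not tested.

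Replicate numbers 1, 3 and 4 occur in both xenograft groups, but same-numbered arrays did not deviate together (correlations of deviations 0.016, -0.163 and -0.104), and no parental array correlated best with the resistant array of its own number, so the numbers are not read as pairs. With the replicate number as a block, the gene count was 2, both among the 16, and the list count 11. Of the 12 list calls 10 were kept, those of cholesterol synthesis (adjusted p = 0.155) and early response (0.429) were not, and xenobiotic uptake and metabolism was added (0.0281). At the level of genes, none of the 16 genes and 12 lists past the threshold changed direction under any alternative, while lists that did not pass could, such as drug efflux transporters, with a mean of -0.04 that became 0.04 with the mean of probe sets per gene. Counted once per gene and alternative, the calls of the 16 genes were kept in 153 cases and lost in 133. Counted once per list and alternative, those of the 12 lists were kept in 152 and lost in 76. Dim signal limits MAML2, VLDLR, GJA1, SERPINE2, DDX60, CMPK2 and MBL2, whose parental levels lay below the array median.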

Other observations

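The comparison of lists between the settings was chosen after the data had been seen. Some lists had opposite signs in the settings: genes of the unfolded protein and integrated stress responses had a median of 0.24 in xenografts and -0.95 in Huh7, and interferon-stimulated genes -0.22 and 0.08. A camera test of these differences was run and is not used here, since Huh7 had 1 array per group. Within the first list the endoplasmic reticulum chaperone HSPA5 differed by 0.23 in xenografts and -1.10 in Huh7, the stress factor DDIT3 by 0.62 and -1.43, and the glutathione-degrading enzyme CHAC1 by 0.98 and -1.09. These 3 genes were chosen after their values were seen, and their xenograft changes did not pass. VLDLR, the 1 member of that list past the threshold in xenografts, had the same sign in both settings (1.38 and 0.76).

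Genes of the hypoxia response had medians of 0.30 in xenografts, a shift that did not pass with an estimated correlation (adjusted p = 0.703), and 0.83 in Huh7, and whether the settings share it was not tested. Of the 4 members named by the rule, EGLN3 differed by 1.52 and 3.38 and INSIG2 by 0.57 and 0.17, while VEGFA (0.48 and -0.72) and STC2 (1.15 and -0.48) had opposite signs.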
